A study of Daphnia magna with 48 samples.

How the data were processed

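The measurements were gene expression ratios from 48 2-colour Agilent arrays of Daphnia magna, a freshwater water flea. Per the labels' protocols, newborn daphnids were exposed for 96 h to each chemical at its EC10, the concentration that immobilised 10% of animals in separate 96 h tests, and whole-body total RNA was extracted from 30 pooled animals per replicate at day 4. Labelling started from 100 ng of RNA. The labels give a renewal interval of 48 h for the experiments with the 4 anilines and none for the others. Comparisons of anilines with other chemicals therefore also differ in this recorded condition. Per the labels, each array held a sample in Cy3 or Cy5 and a universal reference, mixed from aliquots of control and exposed samples, in the other dye. The 8 chemicals each had a control group of their own, which gave 16 groups of 3 biological replicates. The sample was in Cy5 on 24 arrays and in Cy3 on 24. Each group held both dyes.

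The deposited values are log ratios of sample and reference, normalized by the authors, in 1 table of 6006 Daphnia probes and 27 control rows with 0 missing values. That the unit is log2 was inferred from the values. Probe numbers ran to 15415, so the table may hold only part of the array's probes. Background correction, normalization, probe filter and scanner are not given in the sources used here. Array medians lay between -0.02 and 0.01, so each array was centred, and the SD over probes within an array ranged from 0.23 to 0.68. Brightness is not part of a ratio table, so no probe could be judged against background and no depth can be given. The number of arrays limits the precision.

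The direction of the ratios was examined first. Arrays of opposite dye within a group had a median r of 0.44 over probes, above 0, so by the rule set beforehand the table was taken as already turned and was left as deposited. A labelled spike-in row changed sign with the dye on 48 of 48 arrays, with a mean of 3.05 ± 0.64 (SD, n = 24) where the sample was in Cy5 and -3.58 ± 0.62 (SD, n = 24) where it was in Cy3, which shows that swapped arrays had been turned. The overall sign is likely sample over reference and no label settles it. Its basis is that the mean over samples of a ratio to a pooled reference should lie near 1: among 420 probes with an SD of 0.6 to 1, the median log2 of that mean was -0.07 as deposited and 0.43 with the sign turned, and among 90 probes with a larger SD it was 0.31 and 0.68. Probes of lower SD did not favour this reading: the median absolute log2 of the mean was 0.0697 as deposited and 0.0653 turned for 4094 probes with an SD under 0.3, and 0.153 and 0.148 for 1402 probes with an SD of 0.3 to 0.6. Of 1912 probes with an SD of 0.3 or more, 57.6% were closer to 1 as deposited. With the sign turned, every rise reads as a fall and every count of called probes stays as it is. Of 552 pairs of arrays of the same dye, 5 had r under -0.3, the lowest -0.41. The labels state the dyes and these pairs differed in chemical, so the direction was kept.

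The 6006 probes were fitted with limma 3.58.1 in R 4.3.3. The model held 16 group means and a dye covariate over all 48 arrays, with 31 residual degrees of freedom and 3.65 prior degrees of freedom, and moderated tests were adjusted by Benjamini-Hochberg within each comparison. A probe is called when its adjusted p is under 0.05. Every adjusted p printed here is from limma, and all tests are two-sided. Contrasts were each chemical against its own control, the mean effect of the 2 non-polar and of the 5 polar narcotics, the differences between these classes, between the 7 narcotics and cadmium, between the alcohols, between the 4 anilines and between 3,4-dichlorophenol and 3,5-dichloroaniline. F tests covered differences among the 4 anilines and among the 8 control groups. A dye effect was called on 2115 probes (35.2%), with a median absolute size of 0.10 over all probes. Confidence intervals are 95%. Correlations of effects are over probes, which are not independent replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

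The fit was tested on simulated data with 200 of 6006 probes changed, 10 tables per chemical. Errors were drawn independently for each array. With the same spread in every experiment, 3.54% to 5.86% of calls were false. With each chemical's own spread, 28.8% of calls were false for 3-chloropropanol, 26.3% for 4-chloroaniline, 13.7% for aniline and 4.14% for 3,5-dichloroaniline, and at most 2.36% for the remaining chemicals. The model pools the spread over all experiments, so it understates the error of those with noisier arrays. Fitting only a chemical's own 6 arrays gave 4.56% false calls for 3-chloropropanol and 6.63% for 4-chloroaniline. Array weights gave 4.05% to 6.18% by chemical. In the measured data they also weighted the nearly identical 3-chloropropanol controls 1 and 3 most within that chemical (3.16 and 4), a likeness that independent simulated errors do not contain. Aniline control 2 was weighted at 3.73, beside 0.252 and 0.184 for controls 1 and 3, while the simulation gave arrays of a chemical equal spread. In that second simulation the fit of all arrays called 90.1% to 91.8% of the 2-fold changes, by chemical.

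Probe identifiers were looked up in the RefSeq gene table of the organism and 0 matched. The files do not pair probes with gene names, so probes are given by identifier, and the 26 gene lists fixed beforehand could not be tested, nor could probes be averaged by gene. By the rule set before the data were examined, at most 2 probes that rose and 2 that fell are named per comparison: those with the largest absolute change among the 12 largest called ones whose exposed values all lay on one side of the control values, or, for class means, with the same sign in each member. Where fewer than 5 probes were called, those with the smallest p are given as values. Only some of the probes picked in these ways are printed below, and not always the largest. Counts of named probes under the alternatives include the unprinted ones. A probe singled out for another reason is marked as such.

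Alternatives chosen before the data were examined were no dye covariate, only the arrays of the compared groups, replicate number as a block, arrays scaled to equal spread, quantile normalization, the more variable part of the probes, array weights, robust moderation and leaving out each array in turn. Filters on missing values removed no probe and were not run. Separate fits within Cy3 and within Cy5 samples, counting a pair of 3-chloropropanol controls as 1 sample, and leaving 3-chloropropanol out were added after seeing the data.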

Results

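Gene expression was measured in young Daphnia magna after 96 h at the EC10 of 8 chemicals. Isobutanol and 3-chloropropanol are aliphatic alcohols and served as non-polar narcotics, chemicals whose baseline toxicity comes from dissolving in membranes. Aniline, 4-chloroaniline, 3,5-dichloroaniline, 2,3,4-trichloroaniline and 3,4-dichlorophenol are substituted benzenes and served as polar narcotics. Cadmium, a toxic metal, stood outside both classes. Each chemical had 3 exposed and 3 control arrays of its own, each from 30 pooled animals, and each array gave the log2 ratio of 6006 probes against a common reference. The ratios are likely sample over reference, as inferred from the balance of the more variable probes around the pooled reference, so that rises and falls below rest on that reading. Levels below are log2 ratios with their SD (n = 3), and changes are log2 fold changes with their SE.

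Many probes were called between exposed and control animals for isobutanol, 3-chloropropanol, 2,3,4-trichloroaniline, 3,4-dichlorophenol and cadmium. At most 2 probes passed the test for each of aniline, 4-chloroaniline and 3,5-dichloroaniline, which does not show that the other probes were unchanged. For 3-chloropropanol, parting the arrays by dye called 1463 probes and parting them by exposure 524, so its calls are less secure. The typical 95% confidence interval of a probe's change was ± 0.28 on the log2 scale for each chemical. This width is the same for all because the fit pools the spread. The residual SD was 0.19 for isobutanol but 0.30 for 3-chloropropanol, 0.29 for 4-chloroaniline and 0.26 for aniline, for which the interval is too narrow.

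**Figure D1:**
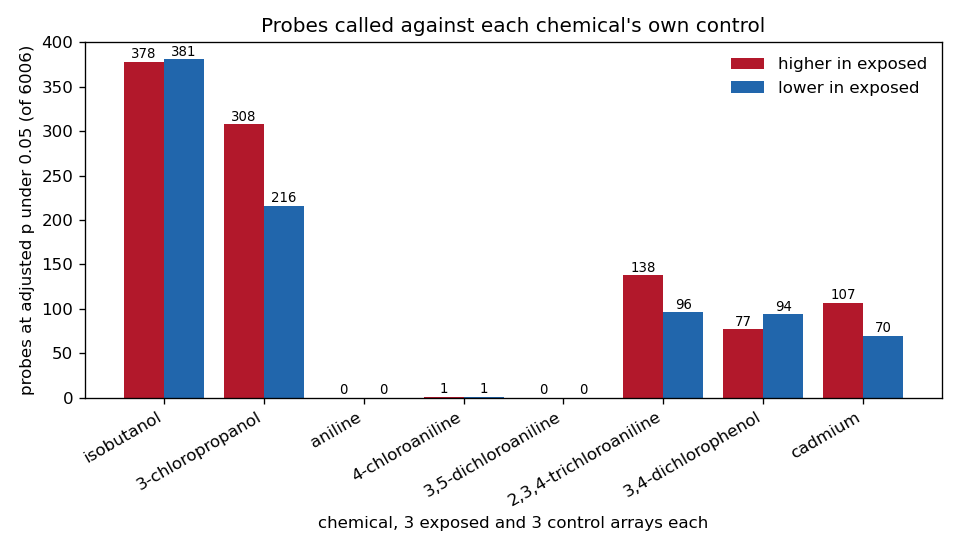
Bars give the number of probes called higher (red) or lower (blue) in exposed than in control animals for each chemical, out of 6006, at an adjusted p under 0.05. Isobutanol had 378 higher and 381 lower probes, and aniline and 3,5-dichloroaniline had 0.

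Isobutanol gave the most calls of the 8 chemicals in this fit. Of 759 called probes, 378 rose and 381 fell, and 107 rose and 65 fell by at least 2-fold. Probe DM07052P1 rose by 4.90 ± 0.43, from -1.55 ± 0.27 in controls to 3.43 ± 0.28 in exposed animals (adjusted p = 3.5e-10). The same probe did not pass the threshold with any other chemical. Probe DM01862P3 fell by 6.76 ± 0.82, from -0.14 ± 0.14 to -7.04 ± 0.37 (adjusted p = 2.16e-07). Probe DM03618P2 fell by 6.09 ± 0.88, from -0.01 ± 0.19 to -6.30 ± 0.61 (adjusted p = 4.66e-06). The count fell to 230 when arrays were scaled to equal spread, to 142 with quantile normalization, to 505 without control replicate 1 and to 481 without control replicate 2, and array weights gave 1755.

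For 3-chloropropanol 524 probes were called, of which 308 rose and 216 fell. Probe DM01862P3 fell by 6.15 ± 0.82, to -6.57 ± 0.66 in exposed animals from -0.28 ± 0.59 in controls (adjusted p = 5.99e-06), and probe DM08009P2 fell by 5.90 ± 0.75, to -6.19 ± 0.55 from -0.29 ± 0.58 (adjusted p = 2.77e-06). Probe DM08113P2 rose by 3.32 ± 0.61, from -2.84 ± 0.50 to 0.34 ± 1.83 (adjusted p = 0.000434). Its 3 exposed values differed widely, at -0.62, -0.81 and 2.45, the last on the only exposed array with the sample in Cy5.

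The 3-chloropropanol arrays fell apart by dye. Control replicates 1 and 3, both in Cy5, correlated at r = 0.94 over probes and at 0.11 and 0.12 with control replicate 2, which was in Cy3. Exposed replicates 1 and 2, both in Cy3, correlated at 0.84 with each other and at 0.28 and 0.24 with exposed replicate 3. The 3 Cy3 arrays correlated with 3,4-dichlorophenol arrays of the same treatment at a mean r of 0.70 (0.57 to 0.84), close to the 0.66 (0.52 to 0.77) within the 3,4-dichlorophenol groups. The difference between control replicates 1 and 3 had an SD of 0.133 over probes, against 0.218 to 0.520 in the other 15 pairs of replicates of the same dye. Whether these 2 arrays hold separate samples cannot be read from the ratios. Counted as 1 sample, they gave 260 called probes, a choice made after seeing the data. Only the 6 arrays of this experiment gave 163 probes, 132 of them among the 524. The count was 271 without control replicate 1, 269 without control replicate 3, 988 without control replicate 2, 979 without exposed replicate 3, 323 with quantile normalization (131 higher and 192 lower, which turned the balance) and 2530 with array weights. In simulated tables with this chemical's own spread and 200 changed probes, 28.8% of calls were false.

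**Figure D2:**
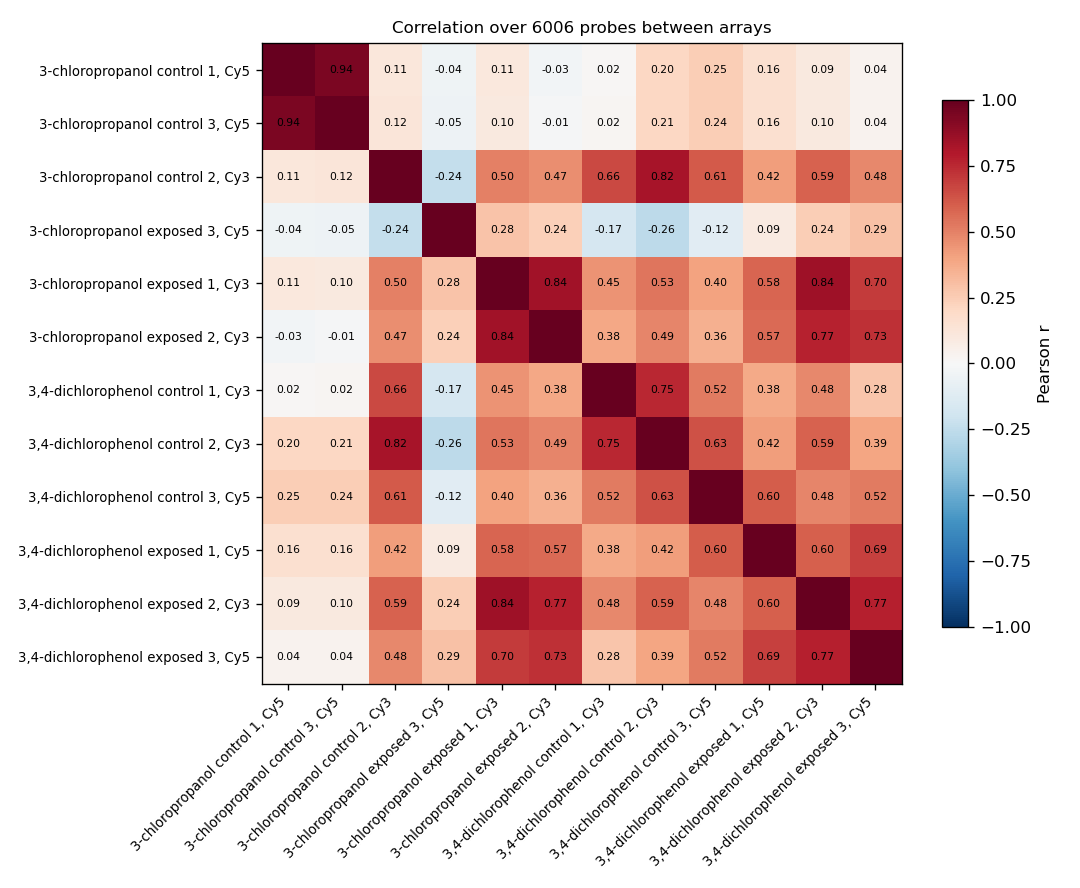
Each cell gives Pearson's r over 6006 probes between arrays of 3-chloropropanol and 3,4-dichlorophenol, ordered by chemical, with treatment, replicate and the sample's dye on both axes. The 3-chloropropanol controls 1 and 3 stand at 0.94 with each other, and the Cy3 array of control 2 stands at 0.82 with control 2 of 3,4-dichlorophenol.

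Aniline gave 0 called probes by limma, with 371 at an unadjusted p under 0.05 where chance gives 300.3, and a smallest adjusted p of 0.482. 3,5-Dichloroaniline also gave 0, with 265 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. 4-Chloroaniline gave 2 called probes and 603 at an unadjusted p under 0.05. Probe DM07251P2 was higher by 1.53 ± 0.20, at 0.48 ± 0.01 in exposed animals and -0.97 ± 0.13 in controls (adjusted p = 2.44e-05), and probe DM03126P4 was at -0.81 ± 0.16 against controls, at -0.10 ± 0.35 and 0.64 ± 0.17 (adjusted p = 0.028). DM07251P2 rose with 2,3,4-trichloroaniline, by 1.49 ± 0.20, and with cadmium, by 2.29 ± 0.20, and fell by 0.67 ± 0.20 with 3-chloropropanol. Array weights gave 623 probes for aniline, 11 for 4-chloroaniline and 41 for 3,5-dichloroaniline. Aniline had 28 when arrays were scaled to equal spread, 35 with quantile normalization and 114 without control replicate 1. 4-Chloroaniline had 0 from its own 6 arrays, where DM07251P2 had an adjusted p of 0.134. DM03126P4 did not pass without the dye covariate (adjusted p = 0.201), with arrays scaled to equal spread (0.117), or without control replicates 1 (0.143) and 2 (0.235) and exposed replicates 2 (0.131) and 3 (0.185). Leaving out 1 of its arrays gave 4, 1 and 89 without control replicates 1, 2 and 3, and 26, 7 and 1 without exposed replicates 1, 2 and 3. In simulated tables with its own spread, 26.3% of the calls for 4-chloroaniline were false, and 13.7% for aniline, while array weights gave 5% and 5.37%. Those tables held 200 changed probes, so their false shares need not hold for lists of 2 and 0 calls. The tables also gave all arrays of a chemical the same spread. The measured weights of aniline control replicates 1, 2 and 3 were 0.252, 3.73 and 0.184, so the 623 leaned mostly on 1 control array. The 0 for aniline depends on the weighting, and the simulation does not vouch for the 623.

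2,3,4-Trichloroaniline changed 234 probes, of which 138 rose and 96 fell. Probe DM10770P3 rose by 2.56 ± 0.28, from -0.86 ± 0.13 to 1.71 ± 0.24 (adjusted p = 6.78e-07). Probe DM08108P3 rose by 2.20 ± 0.35, from -0.96 ± 0.04 to 1.20 ± 0.13 (adjusted p = 0.000153). Probe DM00126P2 fell by 3.66 ± 0.63, from 0.26 ± 0.55 to -3.39 ± 0.86 (adjusted p = 0.000386). It also fell by 3.40 with isobutanol, fell by 3.84 with 3-chloropropanol and fell by 2.52 with cadmium. The count was 134 when arrays were scaled to equal spread and 891 with array weights. It was 85 and 97 without control replicates 1 and 2, and 129, 75 and 142 without exposed replicates 1, 2 and 3.

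3,4-Dichlorophenol changed 171 probes, of which 77 rose and 94 fell. Probe DM01852P3 rose by 2.07 ± 0.31, from -0.18 ± 0.47 to 1.84 ± 0.68 (adjusted p = 4.18e-05). Probe DM08009P2 fell by 3.92 ± 0.75, from -0.68 ± 0.36 to -4.60 ± 2.85 (adjusted p = 0.00133). The wide spread came from exposed replicate 1, at -1.42, beside -5.45 and -6.92 in the other exposed replicates. The count was 37 from the 6 arrays of this experiment alone, where DM01852P3 (adjusted p = 0.112) and DM08009P2 (adjusted p = 0.232) did not pass, 90 when arrays were scaled to equal spread, 96 with quantile normalization and 639 with array weights. It was 98 and 110 without control replicates 1 and 2, and 82 and 98 without exposed replicates 1 and 3.

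Cadmium changed 177 probes, of which 107 rose and 70 fell. Probe DM11286P2 rose by 3.01 ± 0.25, from -0.62 ± 0.16 to 2.39 ± 0.37 (adjusted p = 1.89e-10), and fell by 1.07 ± 0.25 with 2,3,4-trichloroaniline (adjusted p = 0.0117). Probe DM02667P2 rose by 3.11 ± 0.51 with cadmium, from -1.57 ± 0.37 to 1.47 ± 0.31 (adjusted p = 0.000106), and fell by 3.58 ± 0.51 with isobutanol and by 1.82 ± 0.51 with 3,4-dichlorophenol. The isobutanol controls of this probe stood at 2.81 ± 0.19, above the -1.57 to 1.12 of the other control groups. Isobutanol-exposed animals stood at -0.69 ± 0.09, within that range. Probe DM01862P3 fell by 3.76 ± 0.82 with cadmium (adjusted p = 0.0038), a call that ended without exposed replicate 1 (-2.66, adjusted p = 0.0932) and in the 6 arrays of this experiment alone (-3.49, adjusted p = 0.157). The count was 322 when arrays were scaled to equal spread, 154 (74 higher and 80 lower) with quantile normalization, 678 with array weights and 114 without exposed replicate 2.

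**Figure D3:**
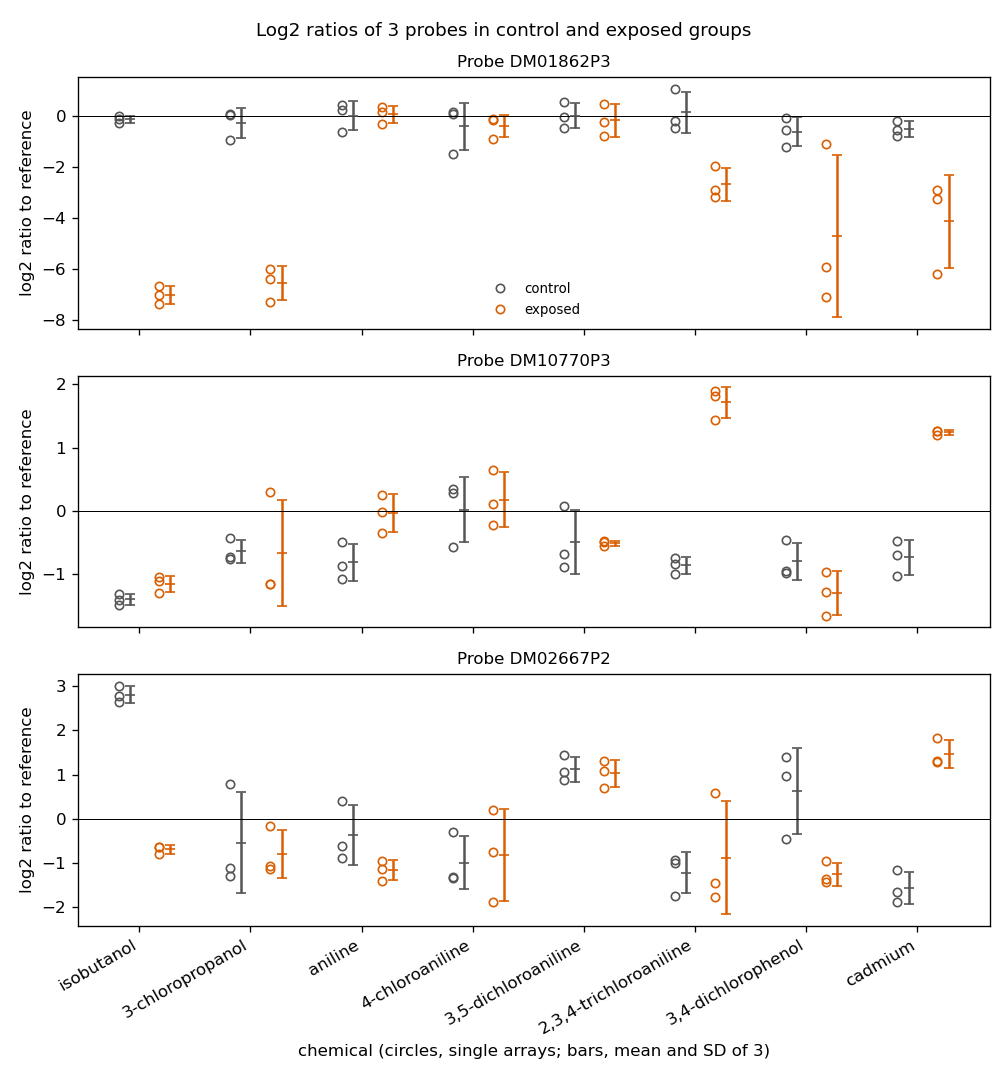
Circles give the log2 ratio of each array for 3 probes, in control (grey) and exposed (orange) groups of the 8 chemicals, and bars give the mean and SD of 3 arrays. DM01862P3 stands at -7.04 in animals exposed to isobutanol and at 0.05 in those exposed to aniline. DM02667P2 rises with cadmium and falls with isobutanol, whose controls at 2.81 stand above the other control groups.

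The series set non-polar against polar narcotics. The mean effect of the 2 alcohols passed the threshold on 874 probes, with 496 higher and 378 lower, and 832 of these had the same sign for both alcohols. Choosing probes by their mean effect favours equal signs, so this share is raised by the choice. Of the probes called higher and lower for isobutanol, 68.8% and 74.0% had the same sign with 3-chloropropanol. In the reverse direction the shares were 76.0% and 69.0%. The mean effect of the 5 polar narcotics passed on 87 probes, with 65 higher and 22 lower, of which 21 had the same sign for all 5 chemicals. Probe DM07391P2 was one of the 21, with a mean rise of 0.80 ± 0.10 (adjusted p = 9.92e-06), made of 0.50 for aniline, 0.70 for 4-chloroaniline, 0.53 for 3,5-dichloroaniline, 1.28 for 2,3,4-trichloroaniline and 0.97 for 3,4-dichlorophenol. Of these 5 only the last 2 passed on their own, and it rose by 1.96 with isobutanol and by 1.66 with cadmium as well. The alcohol count was 511 when arrays were scaled to equal spread, 299 with quantile normalization and 2213 with array weights, and the polar count was 41 (36 higher) with scaling to equal spread and 239 with array weights.

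The difference between the classes itself was called on 324 probes, with 148 higher and 176 lower in polar than in non-polar narcotics. The labels give a renewal for the anilines and none for the alcohols, so class and renewal partly coincide. Probes DM01862P3 and DM08009P2 differed by 5.01 ± 0.69 (adjusted p = 1.11e-05) and 4.70 ± 0.63 (adjusted p = 1.01e-05), having fallen further with the alcohols. Both were also called lower with 3,4-dichlorophenol (-4.24 and -3.92) and 2,3,4-trichloroaniline (-2.97 and -2.56). With aniline, 4-chloroaniline and 3,5-dichloroaniline DM01862P3 had 0.19, 0.16 and -0.34 and DM08009P2 had 0.39, 0.26 and -0.24, none called. The polar mean thus averages chemicals with and without a fall. Probe DM07052P1 differed by -2.43 ± 0.37 (adjusted p = 3.85e-05), and it rose with isobutanol alone. That call ended with quantile normalization (-0.96, adjusted p = 0.484). The count was 129 when arrays were scaled to equal spread, 39 with quantile normalization (29 higher and 10 lower, which turned the balance), 1111 with array weights and 215 without isobutanol control replicate 1.

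The mean effect of the 7 narcotics differed from that of cadmium on 56 probes, 23 higher and 33 lower. Probe DM07431P1 differed by 1.90 ± 0.25 (adjusted p = 7.47e-06). It rose by 1.37 with isobutanol, 0.74 with 3-chloropropanol and 1.46 with 2,3,4-trichloroaniline and fell by 1.32 with cadmium. DM02667P2 differed by -3.98 ± 0.55 (adjusted p = 1.48e-05) and DM11286P2 by -2.97 ± 0.27 (adjusted p = 5.32e-09). The count was 35 without the dye covariate, 139 when arrays were scaled to equal spread, 30 with quantile normalization (16 higher and 14 lower), 356 with array weights and 28 without cadmium exposed replicate 2.

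The alcohols differ in carbon skeleton and in a chlorine on 3-chloropropanol. Their effects differed on 326 probes, with 158 higher and 168 lower for 3-chloropropanol. Probe DM12053P2 rose by 2.06 ± 0.29 with isobutanol and fell by 2.01 ± 0.29 with 3-chloropropanol, a difference of -4.06 ± 0.41 (adjusted p = 3.03e-08). Its 3-chloropropanol controls stood at 1.29 ± 0.19, above the -0.95 to -0.11 of the other control groups. Animals exposed to 3-chloropropanol stood at -0.73 ± 0.53, within the range of those other controls, so the fall rests on an unusual control level. DM07052P1 differed by -4.73 ± 0.61 (adjusted p = 4.24e-06), and this call ended with quantile normalization (-2.86, adjusted p = 0.155). The count was 29 (6 higher) when arrays were scaled to equal spread, 26 (6 higher) with quantile normalization, 181 without the dye covariate, 154 from the 12 arrays alone, 200 among the more variable probes, 2299 with array weights and 155 with the similar 3-chloropropanol controls counted as 1 sample. It was 145 and 160 without isobutanol control replicate 2 and exposed replicate 1. It was 156, 772 and 147 without 3-chloropropanol control replicates 1, 2 and 3, and 182, 206 and 700 without exposed replicates 1, 2 and 3.

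The anilines differ in their number of chlorine atoms. An F test found differences among the 4 effects on 47 probes, and the linear trend with chlorine number was called on 34, of which 21 rose and 13 fell. Probe DM00126P2 had a trend of -1.35 ± 0.29 per chlorine (adjusted p = 0.0342), but its effects were 0.42, 0.58 and -0.71 with aniline, 4-chloroaniline and 3,5-dichloroaniline, none called, and -3.66 with 2,3,4-trichloroaniline. The trend of DM00126P2 did not pass without aniline control replicates 1 (adjusted p = 0.0574) and 3 (0.0507) and exposed replicates 1 (0.0983) and 2 (0.0586), or without 2,3,4-trichloroaniline control replicate 2 (0.0771) and exposed replicates 1 (0.0522) and 3 (0.0705). Between pairs, 2,3,4-trichloroaniline differed from aniline on 52 probes (39 higher), from 4-chloroaniline on 80 (63 higher) and from 3,5-dichloroaniline on 32 (23 higher). The effect of 2,3,4-trichloroaniline on probe DM10770P3 exceeded that of 4-chloroaniline (0.18, not called) by 2.38 ± 0.40 (adjusted p = 0.00371; 0.119 from the arrays of both chemicals alone), and that of 3,5-dichloroaniline (-0.04, not called) by 2.59 ± 0.40 (adjusted p = 0.00046).

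The 3 anilines with fewer chlorines were not told apart by limma. The difference between 4-chloroaniline and aniline was called on 0 probes (534 at an unadjusted p under 0.05), as was that between 3,5-dichloroaniline and aniline (334) and that between 3,5-dichloroaniline and 4-chloroaniline (521). The typical 95% confidence interval of such a difference was ± 0.39 or ± 0.40, so smaller differences stay open. It rests on the pooled spread and is too narrow for the noisier aniline and 4-chloroaniline arrays. Array weights gave 405, 607 and 17 probes, in that order. Scaling to equal spread and quantile normalization gave 26 and 30 for 3,5-dichloroaniline against aniline. Without aniline control replicate 1, 150 probes were called between 4-chloroaniline and aniline, and 1 each without aniline control replicate 3 and 4-chloroaniline exposed replicate 2. Without 4-chloroaniline control replicate 3 and exposed replicate 1, 27 and 4 were called between 3,5-dichloroaniline and 4-chloroaniline. Without aniline control replicate 3, 1 was called between 3,5-dichloroaniline and aniline.

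Single arrays and settings weighed on the other aniline counts. With quantile normalization and with array weights the trend was called on 175 and 441 probes and the F test on 167 and 1486, and from the 24 aniline arrays alone on 14 and 21. The trend gave 9, 76 and 3 without aniline control replicates 1, 2 and 3, and 4, 5 and 21 without its exposed replicates 1, 2 and 3. It gave 13, 9 and 10 without 2,3,4-trichloroaniline control replicates 1, 2 and 3, and 4, 6 and 9 without its exposed replicates 1, 2 and 3. It gave 62 without 4-chloroaniline control replicate 3 and 13 without replicate 1 of either 3,5-dichloroaniline group. The F test gave 137 without aniline control replicate 1, 161 without 4-chloroaniline control replicate 3, 30 without aniline exposed replicate 1 and 76 without 4-chloroaniline exposed replicate 1. It gave 24 and 20 without 2,3,4-trichloroaniline control replicates 1 and 2, and 20, 20 and 23 without its exposed replicates 1, 2 and 3. The comparison of 2,3,4-trichloroaniline with 4-chloroaniline gave 439 without 4-chloroaniline control replicate 3, 177 without its exposed replicate 1, 7, 36 and 22 without its control replicates 1 and 2 and exposed replicate 3, 28 and 32 without 2,3,4-trichloroaniline control replicates 1 and 2, and 32 and 17 without exposed replicates 1 and 2. Only the arrays of both chemicals gave 0, equal spread 7, quantile normalization 32 (20 higher), no dye covariate 34 and array weights 496. The comparison with aniline gave 114 when arrays were scaled to equal spread, 195 with quantile normalization and 503 with array weights, and 33, 15 and 25 without aniline control replicate 3 and exposed replicates 1 and 3, and 34, 20, 21 and 24 without 2,3,4-trichloroaniline control replicates 1 and 2 and exposed replicates 2 and 3. The comparison with 3,5-dichloroaniline gave 20 without the dye covariate, 58 from the arrays of both chemicals alone, 89 with quantile normalization and 628 with array weights, and 20, 18, 19 and 10 without control and exposed replicates 2 and 3 of that chemical, in the order control 2, control 3, exposed 2 and exposed 3, and 15, 12, 18 and 10 without 2,3,4-trichloroaniline control replicates 1 and 2 and exposed replicates 1 and 2.

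3,4-Dichlorophenol and 3,5-dichloroaniline both carry 2 chlorines on the ring and differ in the polar group and the chlorine positions. The labels also give a renewal for 3,5-dichloroaniline and none for 3,4-dichlorophenol, so chemistry and renewal cannot be told apart here. Their effects differed on 52 probes, with 13 higher and 39 lower for 3,4-dichlorophenol. Probe DM01506P1 differed by -2.21 ± 0.40 (adjusted p = 0.00251). It fell by 2.06 ± 0.28 with 3,4-dichlorophenol and had 0.15 ± 0.28 with 3,5-dichloroaniline, and it fell by 2.03 with 3-chloropropanol and by 1.82 with cadmium. The count was 25 without the dye covariate, 34 and 33 with scaling to equal spread and quantile normalization, 28 from the 12 arrays alone and 414 with array weights. It was 29 and 27 without 3,5-dichloroaniline control replicate 2 and exposed replicate 3, and 33 without either of 3,4-dichlorophenol control replicates 1 and 3.

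The 5 chemicals with over 100 called probes changed many of the same probes in the same direction. Between 3-chloropropanol and 2,3,4-trichloroaniline opposite calls were also frequent, at 27 where independent lists give 9.89, beside 28 higher and 22 lower in both. Probes called higher in at least 3 chemicals numbered 71, where independent lists of these sizes give 1.66, and those called lower in at least 3 numbered 61, where they give 0.957. The arrays of 3-chloropropanol and 3,4-dichlorophenol resembled each other above, so their lists may not be independent. This limit also holds for the counts and medians below. A set of 24 probes was called the same way in all 5, with 9 higher and 15 lower. Over these 24, the median change in the shared direction was 1.78 for isobutanol, 1.34 for 3-chloropropanol, 1.21 for 2,3,4-trichloroaniline, 1.24 for 3,4-dichlorophenol and 1.24 for cadmium. These values are raised by the choice of probes called in these chemicals. Over probes called the same way in at least 3 of the other 7 chemicals, the median change in their direction was 1.00 for isobutanol, 0.75 for 3-chloropropanol, 0.44 for 2,3,4-trichloroaniline, 0.76 for 3,4-dichlorophenol and 0.73 for cadmium. By the same choice it was -0.05 for aniline, 0.05 for 4-chloroaniline and 0.07 for 3,5-dichloroaniline. DM01862P3 and DM08009P2 are among the 15 that fell.

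Correlations of the effects over all 6006 probes were highest between 3-chloropropanol and 3,4-dichlorophenol (r = 0.60, Spearman's rho = 0.29), isobutanol and 3,4-dichlorophenol (r = 0.58, rho = 0.42) and the 2 alcohols (r = 0.52, rho = 0.20). The 3-chloropropanol and 3,4-dichlorophenol arrays are those that resembled each other above, and their effects correlated at 0.57 within Cy3 samples and 0.37 within Cy5 samples. By rho, isobutanol with 3,4-dichlorophenol ranked highest and 3-chloropropanol with cadmium next (0.31). Cadmium correlated with isobutanol at 0.45, with 3-chloropropanol at 0.49, with 2,3,4-trichloroaniline at 0.36 and with 3,4-dichlorophenol at 0.48. Every pair with aniline, 4-chloroaniline or 3,5-dichloroaniline lay between -0.13 and 0.15. The pair of 3-chloropropanol and 2,3,4-trichloroaniline lay in that range as well, at 0.08 (-0.01 within Cy3 samples and -0.10 within Cy5 samples). In 100 tables of permuted residual arrays, the 95th percentile of the absolute r of a pair was 0.45 and the largest was 0.80. Of the 28 observed pairs, 5 lay above that percentile and 0 above the largest. The mean over the 28 pairs was 0.15, higher than in each of 99 relabelings of control and exposed arrays within the chemicals, whose highest was 0.09. Over the 5 chemicals with over 100 called probes the mean was 0.41, and it was 0.34 within Cy3 samples and 0.29 within Cy5 samples. With 3-chloropropanol left out, the mean over the rest of these chemicals was 0.41.

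**Figure D4:**
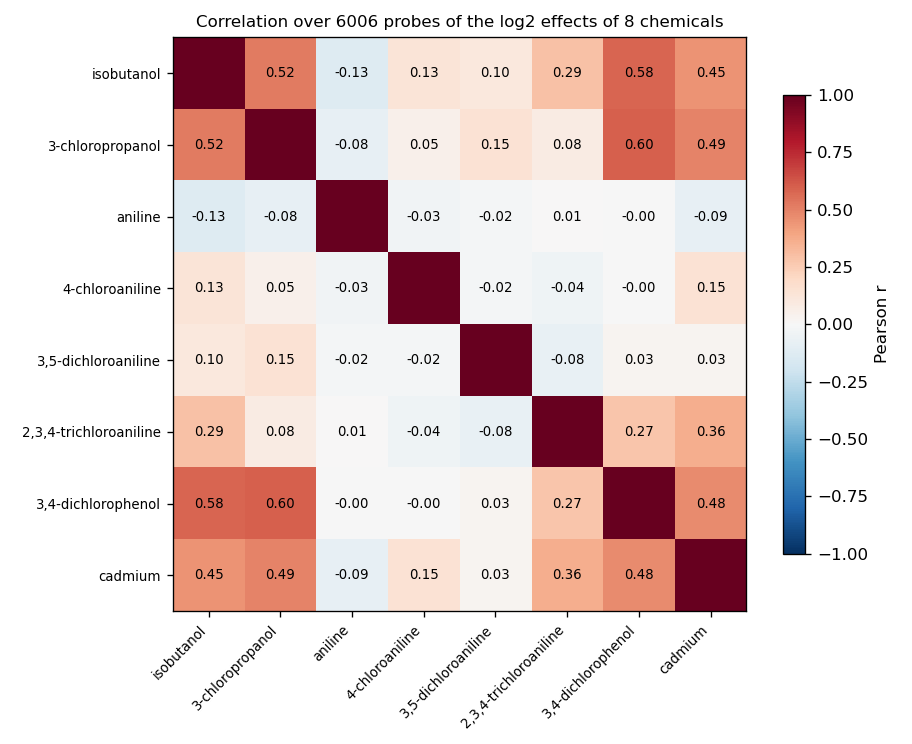
Each cell gives Pearson's r over 6006 probes between the log2 effects of 2 chemicals, each against its own control, on both axes. Isobutanol, 3-chloropropanol, 3,4-dichlorophenol and cadmium lie between 0.45 and 0.60 with each other, and pairs with aniline, 4-chloroaniline and 3,5-dichloroaniline lie between -0.13 and 0.15. 3-Chloropropanol and 2,3,4-trichloroaniline stand at 0.08.

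The 8 control groups differed from each other on 3121 probes (52.0%) by an F test. Each control group belonged to its own experiment, so controls were never pooled across chemicals. With array weights the count was 5236.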

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

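The test of dye bias on the 3-chloropropanol arrays and the counts of other splits were chosen before their results were seen. The other tests of explanations in this part, the fits within a dye and the count with a pair of similar 3-chloropropanol controls as 1 sample were chosen afterwards.

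Differences between the effects of chemicals drew attention because the difference itself was tested. The splits in this paragraph exchanged control and exposed arrays within each chemical, so they ask whether a count arises with no effect of any chemical. Class or chemical membership was not exchanged, so they do not test whether classes or chemicals differ. Polar and non-polar narcotics differed on 324 probes, more than in any of 99 random splits (highest 308, 1 of 100 splits gave as many). A random grouping of the arrays into control and exposed is thus excluded only narrowly. The narcotics differed from cadmium on 56 (2 of 100 as many, highest other 58). The alcohols differed on 326, but 7 of 100 splits gave as many and the highest other gave 783, so chance is not excluded. The anilines differed on 47 by the F test (1 of 100, highest other 23), and the trend with chlorine number was called on 34 (3 of 100, highest other 170). 2,3,4-Trichloroaniline differed from aniline on 52 (3 of 100, highest other 180), from 4-chloroaniline on 80 (5 of 100, highest other 270), where chance is not excluded, and from 3,5-dichloroaniline on 32 (1 of 100, highest other 16). 3,4-Dichlorophenol differed from 3,5-dichloroaniline on 52 (1 of 100, highest other 0). For the trend and for 2,3,4-trichloroaniline against aniline and against 4-chloroaniline, some other splits gave counts several times the real one, which points to structure among those arrays that the groups do not name.

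Other splits were also counted for the remaining comparisons. Chance is excluded for the mean effect of the non-polar narcotics (874; 1 of 100, highest other 355), that of the polar narcotics (87; 1 of 100, highest other 2) and the control groups (3121; 1 of 100, highest other 1201). For the pairs of anilines with 0 calls, 100 of 100 splits gave as many, with highest others of 63 for 4-chloroaniline against aniline, 2 for 3,5-dichloroaniline against aniline and 28 for 3,5-dichloroaniline against 4-chloroaniline. A single chemical has 10 splits of its 6 arrays, too few for a share under 0.05. The real and highest other counts were 759 and 5 for isobutanol, 234 and 0 for 2,3,4-trichloroaniline, 171 and 8 for 3,4-dichlorophenol and 177 and 4 for cadmium, each with 1 of 10 splits as large. They were 0 and 18 for aniline and 0 and 1 for 3,5-dichloroaniline, with 10 of 10, 2 and 38 for 4-chloroaniline, with 5 of 10, and 524 and 1463 for 3-chloropropanol, with 2 of 10. The split with 1463 parts the 3-chloropropanol arrays by dye. Within Cy3 samples 343 probes were called for that chemical and within Cy5 samples 429, of which 143 and 231 were among the 524. Each of these counts sets 1 array against 2 and takes the lone sample to vary like the other groups.

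The split of the 3-chloropropanol arrays by dye has several candidate explanations. The test set for gene-specific dye bias did not decide. The Cy5 minus Cy3 difference of the controls correlated at 0.40 with the dye effect of the other 7 experiments, between the values set for and against it. The 7 other experiments gave 0.37 to 0.69. Removing that dye effect lowered the SD of the difference only from 0.54 to 0.49, the largest of the 8 experiments. A dye bias common to the experiments would make arrays of the same dye more alike. The Cy3 arrays instead correlated at 0.57 to 0.73 with Cy5 3,4-dichlorophenol arrays of the same treatment, and the Cy5 arrays at only 0.09 to 0.29. These values, examined afterwards, argue against such a common bias as the main cause of the split. A dye bias particular to the 3-chloropropanol arrays stays open. The Cy3 arrays could hold 3,4-dichlorophenol samples or share animals with them, since their mean r with those arrays was 0.70, at least that within the 3,4-dichlorophenol groups (0.66), and control replicates 1 and 3 may be 1 sample measured 2 times, with an SD of difference of 0.13 below every other pair. A biological difference between replicates was not tested, and which arrays hold the stated samples cannot be settled here.

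The shared direction of 5 chemicals was set against noise, dye bias and the equal effect level of the exposures. Noise shared by whole arrays would give similar correlations after relabeling, but the highest mean r over any 5 chemicals was 0.41 and none of 99 relabelings reached it (highest 0.27). Dye bias would vanish between dyes, but the effect of 1 chemical in Cy3 arrays correlated with that of another in Cy5 arrays at a mean of 0.35, above 0 in 19 of 20 pairs. If all 8 exposures were at their EC10 as labelled, an equal effect level alone would move all 8 chemicals alike, but over probes called the same way in 3 or more of the other 7 the highest median of aniline, 4-chloroaniline and 3,5-dichloroaniline was 0.0674 (0.135 at most with 1 array left out), against 0.439 or more in the 5 (0.433 at least), although single probes overlapped, with an upper quartile of 0.29 for 4-chloroaniline and a lower quartile of 0.19 for 2,3,4-trichloroaniline, so that a bound on quartiles tried before this one was not met. Those 3 chemicals were singled out for their few calls, so the equal effect level is not excluded if their exposures fell below the EC10, and no biological explanation of the shared direction was tested.

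Whether larger spread between replicates contributes to the low counts for aniline, 4-chloroaniline and 3,5-dichloroaniline stays open. The fit pools the spread, so each chemical has the same SE. In simulated tables with each chemical's own spread it still called 90.5%, 90.1% and 91.3% of 2-fold changes, in that order. Those tables held 200 changed probes, and 13.7%, 26.3% and 4.14% of their calls were false. Fits of only the 6 own arrays called 69.9%, 62.4% and 83.5% of the 2-fold changes, and array weights 87.4%, 85.2% and 91.4%. Tables with fewer changes were not simulated, nor were errors shared between arrays. The simulation therefore cannot decide whether spread hid 2-fold changes here. The covariance between effects in Cy3 and in Cy5 arrays, which carries no replicate error on average, was at most -0.0229 in 4-chloroaniline and 3,5-dichloroaniline, whose calls with array weights were 11 and 41, and 0.0721 or more in the 5 chemicals with over 100 called probes (0.0468 at least with 1 array left out). Effects equal in both dyes cannot give a negative covariance, so the error of this measure is not small. With 1 array left out it reached -0.0456 in 4-chloroaniline, so it cannot decide the question. 4-Chloroaniline had 89 calls without its control replicate 3. For aniline the covariance was 0.0137 (0.0351 at most with 1 array left out), but array weights called 623 probes, near the 639 for 3,4-dichlorophenol, and 114 were called without control replicate 1. Aniline control replicates 1 and 3 had weights of 0.252 and 0.184 and correlated at -0.08. Control replicate 2 had a weight of 3.73, so the weighted count for aniline leaned mostly on 1 control array. A smaller response at the EC10, or an exposure that fell below it, may remain; neither was tested, and concentrations were not part of the data.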

How the results depend on the processing

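The directions of named probes held: among 620 of their values under alternatives chosen beforehand that left out no array of the compared groups, 539 kept their side of the threshold, 48 lost it, 33 gained it and 0 reversed. These probes were chosen from the same data for large changes or small p, so reversals were unlikely from the start. Among all called probes the balance of higher and lower did turn in some comparisons, as given below. With 1 array left out, 989 of 1098 kept it, 91 lost it, 18 gained it and 0 reversed. Counts were less stable. Those that differed from the reported ones by over 1.5-fold are given below with the mean correlations of effects that changed, and for each the cause was not tested. Probe brightness was not analysed here, so signal over background could not be examined, and filters on missing values removed no probe and were not run.

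Without the dye covariate, the counts were 1 for 4-chloroaniline, 35 for narcotics against cadmium, 181 for the alcohols, 34 for 2,3,4-trichloroaniline against 4-chloroaniline, 20 for 2,3,4-trichloroaniline against 3,5-dichloroaniline, 25 for 3,4-dichlorophenol against 3,5-dichloroaniline and 28 for the F test of anilines, and the mean r was 0.144 over all chemical pairs and 0.404 over the 5 chemicals. With arrays scaled to equal spread, the counts were 230 for isobutanol, 28 for aniline, 1 for 4-chloroaniline, 134 for 2,3,4-trichloroaniline, 90 for 3,4-dichlorophenol, 322 for cadmium, 511 for the non-polar mean, 41 for the polar mean, 129 for polar against non-polar, 139 for narcotics against cadmium, 29 for the alcohols, 103 for the chlorine trend, 26 for 3,5-dichloroaniline against aniline, 114 for 2,3,4-trichloroaniline against aniline, 7 for 2,3,4-trichloroaniline against 4-chloroaniline and 34 for 3,4-dichlorophenol against 3,5-dichloroaniline, and the mean r was 0.121 over all chemical pairs and 0.355 over the 5 chemicals. With quantile normalization, the counts were 142 for isobutanol, 323 for 3-chloropropanol, 35 for aniline, 96 for 3,4-dichlorophenol, 299 for the non-polar mean, 39 for polar against non-polar, 30 for narcotics against cadmium, 26 for the alcohols, 175 for the chlorine trend, 30 for 3,5-dichloroaniline against aniline, 195 for 2,3,4-trichloroaniline against aniline, 32 for 2,3,4-trichloroaniline against 4-chloroaniline, 89 for 2,3,4-trichloroaniline against 3,5-dichloroaniline, 33 for 3,4-dichlorophenol against 3,5-dichloroaniline and 167 for the F test of anilines, and the mean r was 0.104 over all chemical pairs and 0.292 over the 5 chemicals. Among the more variable probes, the counts were 4 for 4-chloroaniline and 200 for the alcohols, and the mean r was 0.164 over all chemical pairs and 0.437 over the 5 chemicals. With array weights, the counts were 1755 for isobutanol, 2530 for 3-chloropropanol, 623 for aniline, 11 for 4-chloroaniline, 41 for 3,5-dichloroaniline, 891 for 2,3,4-trichloroaniline, 639 for 3,4-dichlorophenol, 678 for cadmium, 2213 for the non-polar mean, 239 for the polar mean, 1111 for polar against non-polar, 356 for narcotics against cadmium, 2299 for the alcohols, 441 for the chlorine trend, 405 for 4-chloroaniline against aniline, 607 for 3,5-dichloroaniline against aniline, 503 for 2,3,4-trichloroaniline against aniline, 17 for 3,5-dichloroaniline against 4-chloroaniline, 496 for 2,3,4-trichloroaniline against 4-chloroaniline, 628 for 2,3,4-trichloroaniline against 3,5-dichloroaniline, 414 for 3,4-dichlorophenol against 3,5-dichloroaniline, 1486 for the F test of anilines and 5236 for the controls, and the mean r was 0.142 over all chemical pairs and 0.399 over the 5 chemicals. From only the arrays of the compared groups, the counts were 163 for 3-chloropropanol, 0 for 4-chloroaniline, 37 for 3,4-dichlorophenol, 154 for the alcohols, 14 for the chlorine trend, 0 for 2,3,4-trichloroaniline against 4-chloroaniline, 58 for 2,3,4-trichloroaniline against 3,5-dichloroaniline, 28 for 3,4-dichlorophenol against 3,5-dichloroaniline and 21 for the F test of anilines. Over probes called in either chemical of a pair, the mean r was 0.273 over all chemical pairs and 0.579 over the 5 chemicals.

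The share of called probes that were higher changed by over 10 percentage points in these comparisons. With scaling to equal spread it was 100% for 4-chloroaniline (50% as reported), 87.8% for the polar mean (74.7% as reported) and 20.7% for the alcohols (48.5% as reported). With quantile normalization it was 40.6% for 3-chloropropanol (58.8% as reported), 48.1% for cadmium (60.5% as reported), 74.4% for polar against non-polar (45.7% as reported), 53.3% for narcotics against cadmium (41.1% as reported), 23.1% for the alcohols (48.5% as reported) and 62.5% for 2,3,4-trichloroaniline against 4-chloroaniline (78.8% as reported). Without the dye covariate, the share of called probes that were higher was 100% for 4-chloroaniline (50% as reported), 72.7% for the chlorine trend (61.8% as reported) and 36% for 3,4-dichlorophenol against 3,5-dichloroaniline (25% as reported). Among the more variable probes, the share of called probes that were higher was 36.5% for the alcohols (48.5% as reported). With array weights, the share of called probes that were higher was 59.2% for 2,3,4-trichloroaniline against aniline (75% as reported), 53.7% for 2,3,4-trichloroaniline against 3,5-dichloroaniline (71.9% as reported) and 46.6% for 3,4-dichlorophenol against 3,5-dichloroaniline (25% as reported). From only the arrays of the compared groups, the share of called probes that were higher was 35.1% for the alcohols (48.5% as reported), 42.9% for the chlorine trend (61.8% as reported) and 39.3% for 3,4-dichlorophenol against 3,5-dichloroaniline (25% as reported).

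Leaving out each array in turn gave counts of 481 to 592 for isobutanol, 269 to 988 for 3-chloropropanol, 0 to 114 for aniline, 1 to 89 for 4-chloroaniline, 0 to 0 for 3,5-dichloroaniline, 75 to 229 for 2,3,4-trichloroaniline, 82 to 190 for 3,4-dichlorophenol, 114 to 159 for cadmium, 673 to 1053 for the non-polar mean, 66 to 97 for the polar mean, 215 to 424 for polar against non-polar, 28 to 69 for narcotics against cadmium, 145 to 772 for the alcohols, 3 to 76 for the chlorine trend, 0 to 150 for 4-chloroaniline against aniline, 0 to 1 for 3,5-dichloroaniline against aniline, 15 to 69 for 2,3,4-trichloroaniline against aniline, 0 to 27 for 3,5-dichloroaniline against 4-chloroaniline, 7 to 439 for 2,3,4-trichloroaniline against 4-chloroaniline, 10 to 46 for 2,3,4-trichloroaniline against 3,5-dichloroaniline, 27 to 69 for 3,4-dichlorophenol against 3,5-dichloroaniline, 20 to 161 for the F test of anilines and 2522 to 3573 for the controls. The mean r was 0.139 to 0.168 over all chemical pairs and 0.389 to 0.433 over the 5 chemicals.

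Replicate numbers did not pair the samples: 7 of 24 pairs of a control and an exposed array with the same number had deviations that correlated over 0.1 (-0.30 to 0.30), and every control lay closest to its own number in 1 chemical. With the replicate block the counts were 668 for isobutanol, 421 for 3-chloropropanol, 0 for aniline, 7 for 4-chloroaniline, 0 for 3,5-dichloroaniline, 206 for 2,3,4-trichloroaniline, 126 for 3,4-dichlorophenol, 160 for cadmium, 747 for the non-polar mean, 74 for the polar mean, 217 for polar against non-polar, 40 for narcotics against cadmium, 246 for the alcohols, 18 for the chlorine trend, 0 for 4-chloroaniline against aniline, 0 for 3,5-dichloroaniline against aniline, 34 for 2,3,4-trichloroaniline against aniline, 5 for 3,5-dichloroaniline against 4-chloroaniline, 184 for 2,3,4-trichloroaniline against 4-chloroaniline, 12 for 2,3,4-trichloroaniline against 3,5-dichloroaniline, 35 for 3,4-dichlorophenol against 3,5-dichloroaniline and 41 for the F test of anilines, and the mean r was 0.149 over all chemical pairs and 0.415 over the 5 chemicals. With the block the share of called probes that were higher was 28.6% for 4-chloroaniline (50% as reported), 88.9% for the chlorine trend (61.8% as reported) and 91.7% for 2,3,4-trichloroaniline against 3,5-dichloroaniline (71.9% as reported).

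The following alternatives were chosen after seeing the data. Within Cy3 samples, the counts were 379 for isobutanol, 343 for 3-chloropropanol, 5 for 4-chloroaniline, 17 for 2,3,4-trichloroaniline, 25 for 3,4-dichlorophenol, 89 for cadmium, 578 for the non-polar mean, 7 for the polar mean, 34 for narcotics against cadmium, 104 for the alcohols, 1 for the chlorine trend, 2 for 4-chloroaniline against aniline, 2 for 2,3,4-trichloroaniline against aniline, 2 for 3,5-dichloroaniline against 4-chloroaniline, 8 for 2,3,4-trichloroaniline against 4-chloroaniline, 2 for 2,3,4-trichloroaniline against 3,5-dichloroaniline and 0 for 3,4-dichlorophenol against 3,5-dichloroaniline, and the mean r was 0.132 over all chemical pairs and 0.345 over the 5 chemicals. Within Cy5 samples, the counts were 320 for isobutanol, 3 for aniline, 336 for 4-chloroaniline, 76 for 3,5-dichloroaniline, 37 for 2,3,4-trichloroaniline, 77 for 3,4-dichlorophenol, 71 for cadmium, 500 for the non-polar mean, 29 for the polar mean, 18 for narcotics against cadmium, 144 for the alcohols, 20 for the chlorine trend, 81 for 4-chloroaniline against aniline, 9 for 3,5-dichloroaniline against aniline, 8 for 2,3,4-trichloroaniline against aniline, 508 for 3,5-dichloroaniline against 4-chloroaniline, 145 for 2,3,4-trichloroaniline against 4-chloroaniline, 57 for 2,3,4-trichloroaniline against 3,5-dichloroaniline and 86 for 3,4-dichlorophenol against 3,5-dichloroaniline, and the mean r was 0.0862 over all chemical pairs and 0.291 over the 5 chemicals. With the similar 3-chloropropanol controls as 1 sample, the counts were 260 for 3-chloropropanol and 155 for the alcohols. Without 3-chloropropanol, the mean r was 0.118 over all chemical pairs and 0.407 over the rest of the 5 chemicals. Each group holds 1 or 2 arrays per dye, so every fit within a dye sets lone samples against others and takes them to vary like the other groups. Within Cy3 samples, the share of called probes that were higher was 46.9% for 3-chloropropanol (58.8% as reported), 100% for 4-chloroaniline (50% as reported), 94.1% for 2,3,4-trichloroaniline (59% as reported), 28% for 3,4-dichlorophenol (45% as reported), 74.2% for cadmium (60.5% as reported), 85.7% for the polar mean (74.7% as reported), 23.5% for narcotics against cadmium (41.1% as reported), 27.9% for the alcohols (48.5% as reported), 100% for the chlorine trend (61.8% as reported), 100% for 2,3,4-trichloroaniline against aniline (75% as reported) and 100% for 2,3,4-trichloroaniline against 3,5-dichloroaniline (71.9% as reported). Within Cy5 samples, the share of called probes that were higher was 20.5% for 4-chloroaniline (50% as reported), 86.2% for the polar mean (74.7% as reported), 62.5% for 2,3,4-trichloroaniline against aniline (75% as reported) and 31.6% for 2,3,4-trichloroaniline against 3,5-dichloroaniline (71.9% as reported). Of 188 values of named probes under these alternatives, 127 kept their side of the threshold, 53 lost it, 8 gained it and 0 reversed.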

Other observations

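The observations here were chosen after seeing the data. The 15 probes called lower with isobutanol, 3-chloropropanol, 2,3,4-trichloroaniline, 3,4-dichlorophenol and cadmium differed in level between arrays of the same group. Their median log2 ratio was -5.91, -5.15 and -4.65 on the 3 arrays exposed to isobutanol and -5.16, -5.58 and -5.06 on those exposed to 3-chloropropanol. It was -2.31, -1.41 and -2.50 with 2,3,4-trichloroaniline. With 3,4-dichlorophenol it was -4.62 and -5.31 on exposed replicates 2 and 3 and -0.76 on exposed replicate 1, where the mean of the control medians was -0.62. With cadmium it was -4.80 on exposed replicate 1 and -2.65 and -2.50 on the other exposed replicates.

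The 9 probes called higher in the same 5 chemicals did not follow that order. On the 3,4-dichlorophenol array with the smallest fall, replicate 1, their median log2 ratio was 0.93, above the 0.47 and 0.27 of replicates 2 and 3. Their median was 1.11, 1.24 and 1.08 with cadmium and 0.82, 0.94 and 0.79 with isobutanol. It was 0.64, 0.52 and 0.58 with 3-chloropropanol and 0.54, 0.63 and 0.86 with 2,3,4-trichloroaniline. In 2,3,4-trichloroaniline, replicate 3 had both the largest fall and the largest rise. Probe DM08571P2, one of the 9, rose by 2.67 with cadmium and by 1.82 with 2,3,4-trichloroaniline and stood at 1.00 with 4-chloroaniline (adjusted p = 0.0604).

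Of 1287 probes called in at least 1 chemical, 60 were called higher in at least 1 and lower in at least 1 other. The opposite calls were most frequent between 3-chloropropanol and 2,3,4-trichloroaniline, with 27 where independent lists give 9.89, beside 28 higher and 22 lower in both.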
